A study of Homo sapiens with 10 samples.

How the data were processed

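Total RNA was extracted from pieces of human non-small cell lung tumors, and libraries were made with a kit for fixed tissue RNA (Ovation human FFPE RNA-Seq, NuGen), per the labels' protocols. Each tumor had been placed in a high or a low perfusion group by dynamic contrast-enhanced MRI, per the labels. There were 10 libraries, 4 of high and 6 of low perfusion, from 6 tumors. Of the 3 high tumors, 1 gave libraries from 2 regions, and each of the 3 low tumors gave libraries from 2 regions. The strand setting of the counting, and the versions of the tools, are not given in the sources used here, so reads of a gene and of an antisense partner cannot be told apart.

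The submitters' processing notes name TopHat, Cufflinks and Cuffnorm and the human build hg19. The authors deposited a table of fragment counts per locus that had been divided by a factor per library, so its values are a scaled signal and not whole counts. The authors deposited a second table of the same loci as FPKM, which also divides by transcript length. Both tables held 104439 loci, of which 78192 had no gene name and 926 carried several symbols. The loci with no name and those with several symbols took a median of 6.67% and 9.79% of the scaled counts. No coordinates are given here, since the reference annotation in hand was of another build.

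In each library 97.6 to 97.9% of the values above 0 were whole multiples of 1 step, within 0.05 fragment. Dividing by that step gave a depth of 5369186 to 21531638 fragments in the 4 high libraries and 12461985 to 15909736 in the 6 low libraries. Values below 1e-06 were taken as 0, and each library held 16 to 40 such vanishing values above 0. All 45 pairs of libraries were compared before averaging, and 0 pairs held identical values. The lowest chi-square per degree of freedom of any pair was 56.4, far above counting error, so every library was kept.

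Rows of the same gene name were summed, which touched 1323 of the 22666 names. All 69 Y-linked, XIST and TSIX names were left out to protect the donors. For the same reason 9 names with a common germline deletion were left out, a choice made after the data were seen.

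The tumor was the replicate, because perfusion did not vary within a patient. The test planned for whole counts needed another unit than the deposited one, so the planned fallback was used. It was limma's moderated test with an intensity trend (limma 3.58.1 in R 4.3.3) on log2(scaled count + 1), averaged over the libraries of each tumor, 3 high against 3 low. A pseudocount of 1 understates the change of low genes. Genes with a value of at least 10 in at least 3 tumors were tested, which left 16604. Adjusted p-values are Benjamini-Hochberg values with a threshold of 0.05. Fold changes are given as log2 of high over low with the standard error of the limma fit.

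A total of 40 gene lists were fixed, plus a panel of 26 genes of glucose, lactate, pyruvate, hypoxia and vessel biology. The list of mitochondrially encoded messages had 0 measured members, so 39 lists were tested with camera (limma) at a preset inter-gene correlation of 0.01, adjusted over the lists. Camera with an estimated correlation and fry were run beside it. A list score is the mean over its members of the log2 value minus the member's mean over the 6 tumors. Scores were compared by an exact two-sided permutation test over tumors, which cannot go below 0.1 with 3 against 3. The similarity of regions was tested over all ways of pairing the 8 libraries of the 4 tumors with 2 regions. The samples' groups, the lists, the main tests, the rule for named genes and most alternatives were fixed before the data were examined. That plan adjusted over the list alone for the panel only. The same adjustment within the other lists and the permutation test of list scores were not part of it. Over the 39 lists, 47 members passed limma's test adjusted over their list alone, a shared member counted in each list, with no adjustment over the lists.

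The rule named up to 12 genes in each direction with the smallest adjusted p under 0.05 and an absolute log2 fold change of at least 1. Where fewer than 12 passed, it filled the direction with genes of smallest unadjusted p that had a mean log2 CPM of at least 2, an absolute log2 fold change of at least 1 and tumor values that did not overlap between groups. Every gene of the panel and up to 4 members of each list with the smallest unadjusted p could be named too. Sex-linked genes, small RNA and uncharacterised symbols, immunoglobulin and T cell receptor segments, class II HLA beta genes and rows with several symbols were excluded.

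Alternatives were other scalings, other filters, the FPKM table, a single region per tumor, all 10 libraries with or without the tumor as a random effect, and each tumor left out in turn. Pseudocounts of 0.1 and 5, limma-voom on the recovered fragments, the highest locus per name and the inclusion of loci with no name were added after the data were seen. The gene test was tested on simulated data for 16604 genes in this comparison. It called 4 of 50 genes with a log2 change of 1, 33 of 50 with 2, 49 of 50 with 3 and 50 of 50 with 4, with 11 calls among 16374 unchanged genes. In the simulation genes varied independently, the regions of a tumor shared 1 level, and changed genes were drawn above a minimum level. These figures need not hold for correlated genes or for low genes. Tables and plots were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.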

Results

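Gene expression was measured by RNA sequencing in 10 libraries from 6 human non-small cell lung tumors, 3 with high and 3 with low perfusion on dynamic contrast-enhanced MRI, an imaging method that follows an injected contrast agent into tissue. The design asked how transcript levels differed between tumors of high and low perfusion, and its title points to differences in metabolism between and within tumors. Depth was 5369186 to 21531638 fragments per library in the high group and 12461985 to 15909736 in the low group. Averaged per tumor it was 11863297 ± 8535984 (SD, n = 3) against 13874683 ± 306982 (SD, n = 3) fragments, with an exact permutation p of 0.7. Tumors are called high 1 to 3 and low 1 to 3, and the regions of a tumor a and b.

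Between high- and low-perfusion tumors, 0 of 16604 genes passed limma's test at an adjusted p under 0.05. The gene with the smallest p was KIF1A, a motor protein of axonal transport, at 308 ± 72.6 scaled counts in high and 1947 ± 429 in low tumors (SD, n = 3 each), a log2 fold change of -2.54 ± 0.31 (SE). Its limma adjusted p was 0.21. Among the 12 genes named on the lower side, ASPM (-2.10 ± 0.40), CDCA2 (-2.18 ± 0.43), MYBL2 (-1.84 ± 0.37), ESPL1 (-1.80 ± 0.37) and KIFC1 (-1.71 ± 0.36) act in mitosis or the cell cycle. FADS2, a desaturase of polyunsaturated fatty acid synthesis, lay at -1.85 ± 0.34. UCHL1, a deubiquitinase abundant in neurons, lay at -2.37 ± 0.47. The collagen gene COL22A1 (-2.46 ± 0.39), the choline transporter-like gene SLC44A5 (-2.11 ± 0.36), the Polycomb gene CBX2 (-1.99 ± 0.36) and the glycosyltransferase gene B4GALNT4 (-2.33 ± 0.48) completed that side.

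On the higher side, PIGR, the receptor that carries polymeric immunoglobulin across epithelium, stood at 14954 ± 9332 scaled counts in high and 2404 ± 258 in low tumors, a log2 fold change of 2.41 ± 0.53. SCGB3A1, a secretoglobin of airway epithelium, lay at 2.29 ± 0.41. PGC, a protease precursor also made by alveolar type 2 cells, lay at 2.53 ± 0.49, and the folate receptor gene FOLR1 at 2.15 ± 0.37. The mucin gene MUC6 (1.94 ± 0.36), the retinal dehydrogenase gene ALDH1A1 (1.58 ± 0.33), the secreted ribonuclease gene RNASE1 (1.75 ± 0.33) and the transporter gene ABCA8 (2.14 ± 0.36) were also named. The remaining 4 were C16orf89 (2.25 ± 0.39), CCDC129 (2.19 ± 0.43), CRYM (2.62 ± 0.53) and STEAP4 (1.58 ± 0.35). The limma adjusted p of the 12 genes lay between 0.57 and 0.65. At an unadjusted p under 0.05, limma gave 924 genes, 429 higher and 495 lower, where 830 would be expected with no effect. Tumor values did not overlap between the groups for 1840 genes, 11.1% of those tested, where chance gives 10%. With limma-voom on the recovered fragments per tumor, 0 genes passed and 807 had an unadjusted p under 0.05.

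**Figure D1:**
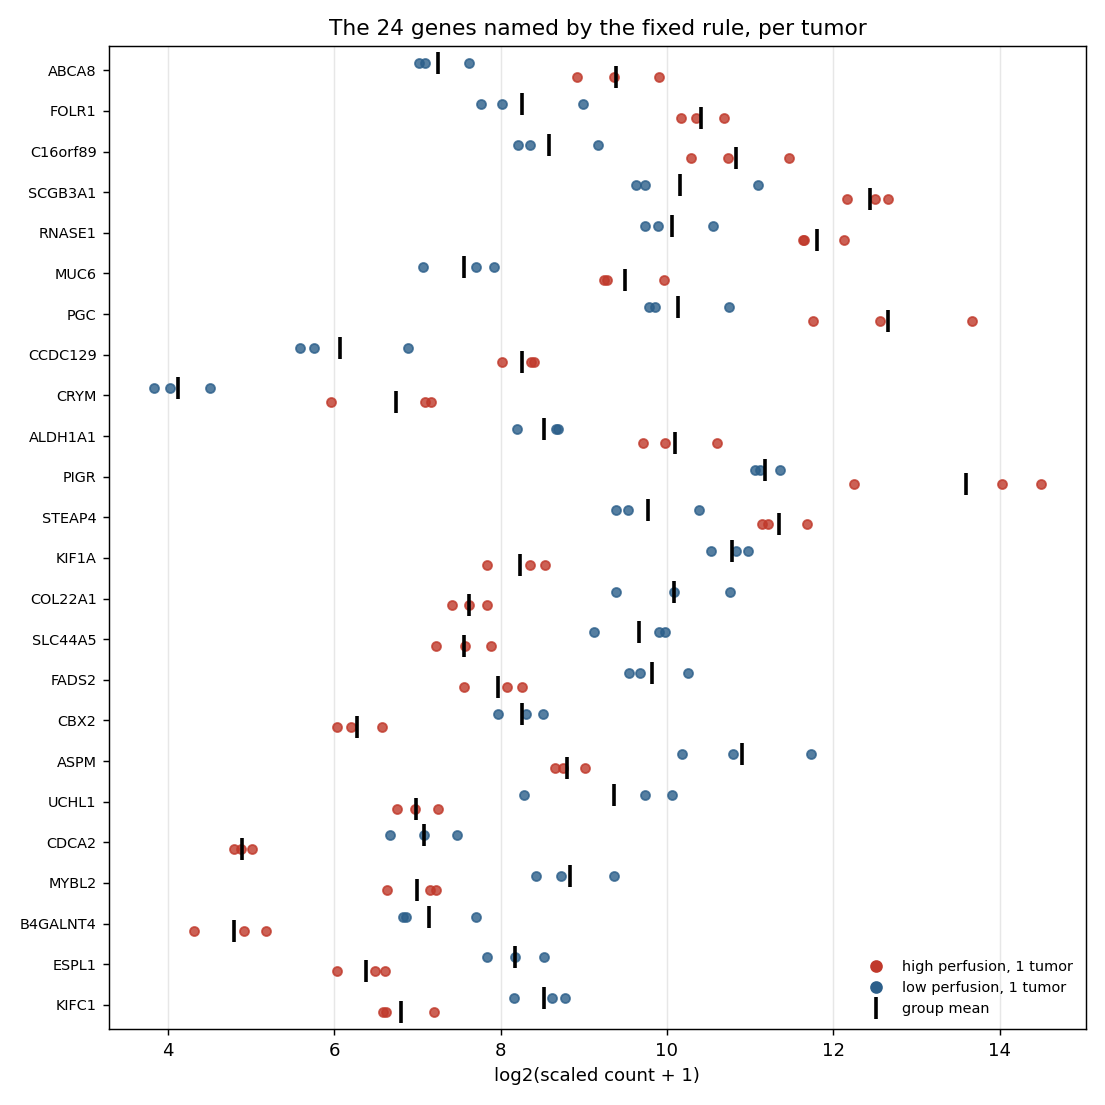
Values of the 24 named genes in the 6 tumors, as log2(scaled count + 1) on the x axis, with 1 point per tumor, red for high and blue for low perfusion, and a bar at each group's mean. The values of the 2 groups do not overlap for any of these genes, which the rule required, and 0 of them passed the adjusted threshold.

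With all 6 tumors, cell cycle genes formed the list with the largest median shift, though without low 1 or low 3 (-1.89 and -1.15) the neuroendocrine median lay further from 0. All 30 measured members had lower values in high perfusion, with a median log2 fold change of -1.58. BIRC5, a mitotic survivin, stood at 52.1 ± 10.5 scaled counts in high and 234 ± 126 in low tumors. TOP2A, a topoisomerase of dividing cells, stood at 759 ± 110 and 3059 ± 1898, and TPX2, a spindle assembly factor, at 200.2 ± 34.1 and 791 ± 454. Adjusted over the list alone, 28 of the 30 members passed limma's test, against 0 when adjusted over all genes tested. The list score was -0.79 ± 0.15 in high and 0.79 ± 0.73 in low tumors (SD, n = 3 each), and the exact permutation p was 0.1, the smallest this design allows. Of the 39 lists, 5 reached that value, and each does so by chance with a probability of 0.1. The others were histones, fatty acid and cholesterol synthesis, red blood cell transcripts and alveolar type 1 markers. Replication-dependent histones, which are made in S phase, were lower in 14 of 14 members with a median of -0.69, and 0 members passed adjusted over the list alone. HIST1H2BG (-1.61 ± 0.51) and HIST1H3B (-1.27 ± 0.44) were among them, and reads of near-identical histone copies may be divided uncertainly. Camera gave adjusted p = 2.13e-31 for the cell cycle and 6.21e-07 for histones, and adjusted p = 0.45 for both with an estimated correlation. For the same lists, fry gave adjusted p = 0.36 and 0.39.

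Across the 39 lists, camera with the preset correlation called 19, of which 11 were higher and 8 lower in high perfusion. Exact permutation p-values of these list scores ran from 0.1 to 0.7, with 0.6 for oxidative phosphorylation and 0.7 for T cells and for B and plasma cells. With an estimated correlation 0 lists passed and 2 had an unadjusted p under 0.05, the cell cycle and red blood cell transcripts. With fry 0 lists passed and 3 had an unadjusted p under 0.05. Each camera call made below with all 6 tumors is therefore given with its adjusted p under the estimated correlation, which was not run for calls with a tumor left out or with a single region. The balance of calls rested on single tumors. It was 7 higher and 12 lower without high 3, 15 and 7 without high 2, and 10 and 4 without low 2. With the first region of each tumor it was 5 and 6. Of the 19 calls, 5 held in each of the 21 alternatives run with the preset correlation, and these were the cell cycle, histones, fatty acid and cholesterol synthesis, glandular epithelial markers and antigen presentation. The correlation estimated for these 5 lists was 0.18 to 0.67, against the preset 0.01. Scores overlapped between the groups for glandular markers (high 1 at -0.29, low 1 at -0.19) and for antigen presentation (high 2 at -0.30, low 1 at 0.11).

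**Figure D2:**
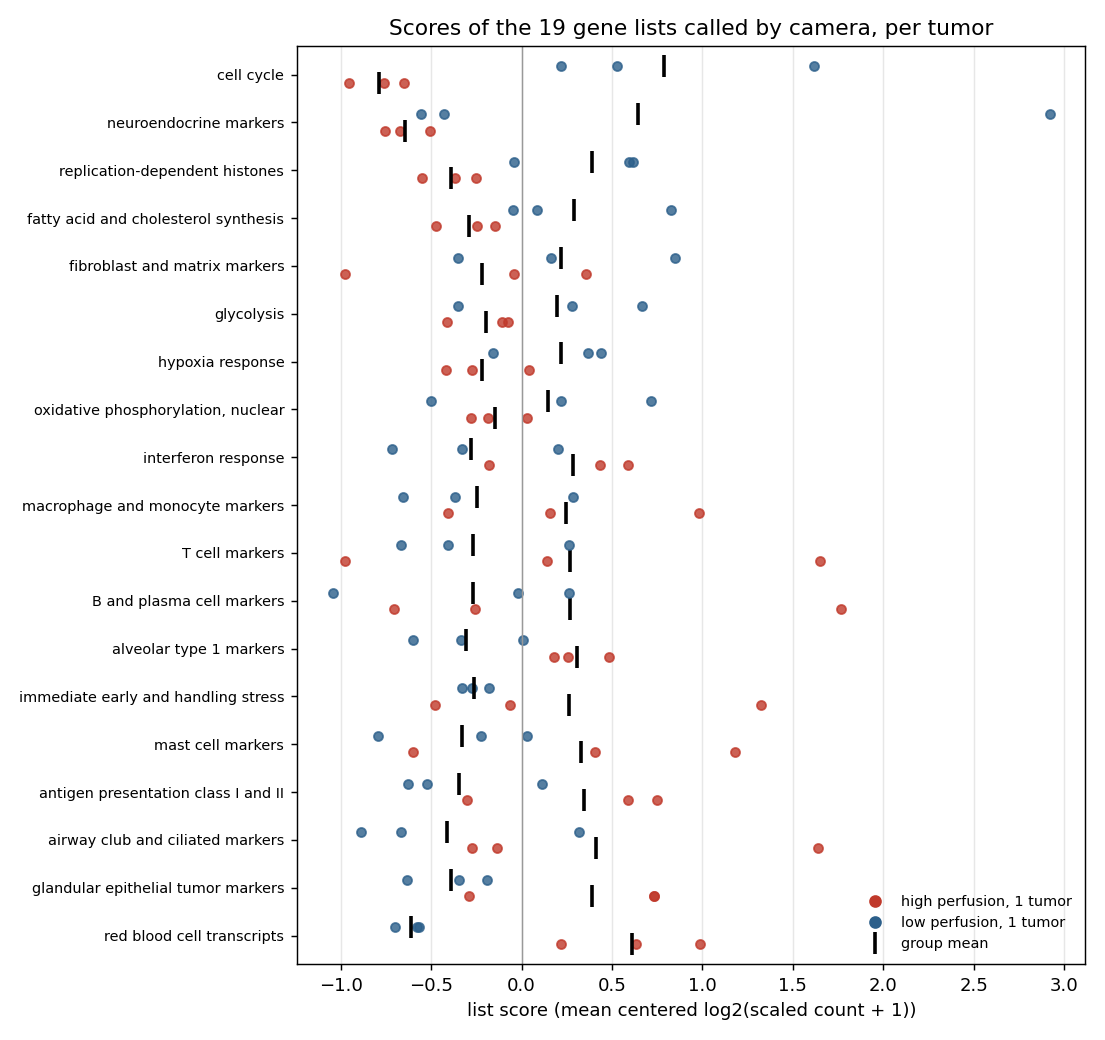
Scores of the 19 lists called by camera with the preset correlation, with the score on the x axis, 1 point per tumor, red for high and blue for low perfusion, and a bar at each group's mean. Cell cycle scores average -0.79 in high and 0.79 in low tumors, while most other lists overlap between the groups.

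Camera called 3 of the 11 metabolic lists, all lower in high perfusion. Fatty acid and cholesterol synthesis was lower in 16 of 19 members with a median of -0.62. It included the elongase ELOVL6 (-1.55 ± 0.46), the squalene synthase FDFT1 (-0.95 ± 0.34), the sterol reductase DHCR7 (-0.99 ± 0.39) and the fatty acid synthase FASN (-0.75 ± 0.34). Glycolysis was lower in 14 of 19 members with a median of -0.44, including GPI (-1.21 ± 0.47), PFKM (-0.80 ± 0.33) and GAPDH (-1.10 ± 0.57). Nuclear genes of oxidative phosphorylation were lower in 29 of 42 members with a median of -0.30, such as COX5A (-0.90 ± 0.47). No member of these 3 lists passed, whether adjusted over the list alone or over all genes. Camera adjusted p-values were 5.13e-05, 0.0059 and 0.0059 in that order, and each list had an adjusted p = 0.82 with an estimated correlation. Without low 3 the medians were -0.26, -0.33 and 0.04, with camera adjusted p-values of 0.0079, 0.16 and 0.90. The glycolysis and oxidative phosphorylation calls also ended without high 1 (-0.35 and -0.25) and without low 2 (-0.34 and -0.22), and without low 1 the medians were -0.79 and -0.59.

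The TCA cycle (median -0.01), pyruvate entry to mitochondria (0.07), fatty acid oxidation and ketone use (-0.02), the pentose phosphate pathway (0.15), serine, glycine and one-carbon metabolism (-0.02) and NRF2 targets (-0.40) were not called by camera with all tumors. With 1 tumor left out, the first 5 medians ranged from -0.05 to 0.07, -0.06 to 0.15, -0.12 to -0.01, -0.01 to 0.40 and -0.25 to 0.07 in that order. Camera called NRF2 targets lower without high 3 (-0.56, adjusted p = 0.015), without low 1 (-0.56, adjusted p = 0.0497) and with the other region of each tumor (-0.57, adjusted p = 0.038), and their median was -0.05 without low 3. Lactate and monocarboxylate handling had a median of 0.04 but a mean of -0.27 and a camera direction of lower, and glutamine and glutamate metabolism had a median of -0.07 but a mean of 0.04 and a camera direction of higher. Neither was called. The lactate median was -0.63 without high 2 and -0.32 without low 2, and the glutamine median ranged from -0.25 without low 1 to 0.22 without low 3. In these lists SUCLG2 lay at 0.74 ± 0.30, the citrate synthase gene CS at -0.77 ± 0.33, SHMT2 at -0.98 ± 0.36, the aldehyde dehydrogenase gene ALDH3A1 at 1.52 ± 0.52 and GPT2 at 1.29 ± 0.59.

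Of the 26 genes of the panel fixed for this question, 0 passed adjusted over the list alone and 0 over all genes tested. By limma, 4 had an unadjusted p under 0.05, all lower in high perfusion. They were the proliferation marker MKI67 (-1.57 ± 0.51), the lactate exporter SLC16A3 (-0.98 ± 0.33), the lactate and pyruvate transporter SLC16A1 (-1.59 ± 0.56) and CA9, a carbonic anhydrase induced by hypoxia (-2.67 ± 1.12). CA9 was listed at 0 in high 2, without which the log2 fold change was -1.5 ± 0.86, and its log2 value in high 1 (3.69) lay above that in low 3 (3.51). Their limma p-values adjusted over the list alone were between 0.16 and 0.26. Lactate dehydrogenase A (LDHA) lay at -0.82 ± 0.44, pyruvate carboxylase (PC) at 0.74 ± 0.59, PDHA1 at 0.09 ± 0.35, the glucose transporter SLC2A1 at -0.11 ± 0.44 and hexokinase 2 (HK2) at 0.11 ± 0.46. Without low 1, 1 panel gene passed adjusted over the list alone, MKI67 at -2.11 ± 0.45. Without low 3, MKI67 lay at -0.95 ± 0.34 and SLC16A1 at -0.93 ± 0.40. LDHA lay at -0.45 without low 3 and -1.28 without low 1, and PC at 0.10 without high 2. PDHA1, SLC2A1 and HK2 changed sign with single tumors left out.

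Endothelial markers did not separate the perfusion groups. Their median log2 fold change was 0.08, with 8 of 16 members on each side, and the scores were 0.03 ± 0.54 in high and -0.03 ± 0.72 in low tumors (SD, n = 3 each, exact permutation p = 0.9). VWF (-0.43 ± 0.41), PECAM1 (0.27 ± 0.47), CDH5 (0.20 ± 0.42) and KDR (-0.04 ± 0.38) lay within about 1 standard error of 0 with all tumors. With 1 tumor left out, VWF ranged from -0.76 to -0.08, PECAM1 from -0.14 to 0.68, CDH5 from -0.28 to 0.47 and KDR from -0.43 to 0.25. Camera called the endothelial list in opposite directions without high 2 (0.30, adjusted p = 0.029) and without low 3 (-0.36, adjusted p = 0.012). The median was -0.28 with the first region of each tumor and 0.43 with the other region, and camera called neither. Angiogenic ligands and receptors (median -0.21) and pericyte and smooth muscle markers (-0.10) were not called with all tumors, and both were called lower without low 3 (-0.58 and -0.33). The angiogenic median was -0.02 without low 2, and the pericyte median 0.34 without high 2 and 0.12 without low 1. VEGFA lay at 0.12 ± 0.62, at 0.82 without high 1 and at -0.60 without high 2. The hypoxia response was lower in high perfusion in 21 of 26 members with a median of -0.31, including EGLN3 (-1.61 ± 0.61) and ERO1L (-0.75 ± 0.37), and 0 members passed adjusted over the list alone. Camera gave adjusted p = 0.0059 for it, and adjusted p = 0.82 with an estimated correlation. The call ended without low 2 (-0.15), without low 3 (-0.19) and with the first region of each tumor alone (-0.23). The median was -0.54 without low 1. Red blood cell transcripts were higher in the 3 members measured of 10 listed, with a median of 1.25, led by CA1 (1.72 ± 0.54) and HBB (1.25 ± 0.66). CA1 passed adjusted over the list alone. Camera gave adjusted p = 0.010, and adjusted p = 0.45 with an estimated correlation. The call ended without low 1 (0.97) and with the first region of each tumor (0.83), and the median was 0.66 without high 3. The red blood cell score differed by a mean of 0.81 between regions of 1 tumor. Between single libraries of different tumors in 1 group it differed by 0.45.

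Markers of glandular epithelium were higher in high perfusion in 10 of 12 members with a median of 1.10, and 4 members passed adjusted over the list alone. Among them were the mucin MUC1 (1.48 ± 0.35), the aspartic protease NAPSA (1.63 ± 0.40) and the phosphate transporter SLC34A2 (1.33 ± 0.38). Alveolar type 1 markers were higher in 7 of 10 members with a median of 0.55, and 2 passed adjusted over the list alone, the water channel AQP5 (2.57 ± 0.62) and HOPX (1.39 ± 0.41). Airway club and ciliated markers were higher in 13 of 15 members with a median of 0.97, and SCGB3A1 was the 1 member that passed adjusted over the list alone. Camera adjusted p-values were 8.4e-05, 0.0059 and 8.04e-04, against adjusted p = 0.45, 0.45 and 0.82 with an estimated correlation. Without high 3 the medians were 0.97, 0.39 and 0.07, and the alveolar type 1 and airway calls ended. The alveolar type 1 call also ended with the first region of each tumor (0.43), and the airway call with the other region (0.38). Without high 2 the glandular median was 0.63, and without low 3 the airway median was 0.57. Alveolar type 2 markers were not called (median 0.30, 8 of 12 higher), although 3 members, PGC, NAPSA and SLC34A2, passed adjusted over the list alone. Camera called that list higher without high 2 (0.53, adjusted p = 0.018), without high 3 (0.43, adjusted p = 0.029) and with the other region of each tumor (0.54, adjusted p = 0.0059), and its median was -0.29 without high 1. The glandular and alveolar type 2 lists share 2 members. Squamous keratinocyte markers had a median of -0.57 and were not called with all tumors. Camera called them lower without high 3 (-0.84, adjusted p = 0.034), without low 2 (-1.14, adjusted p = 0.012) and with the other region of each tumor (-1.32, adjusted p = 0.011), and their median was 0.22 without low 3.

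Neuroendocrine markers were lower in high perfusion in 12 of 12 members with a median of -1.33, led by UCHL1, SCG3 (-1.71 ± 0.90) and CHGA (-1.65 ± 0.94). UCHL1 was the 1 member that passed adjusted over the list alone. Its log2 value was 8.28 in low 1, 9.74 in low 2 and 10.06 in low 3, against 6.75 to 7.24 in the high tumors, so it did not rest on low 2. Camera gave the list adjusted p = 8.4e-05, and adjusted p = 0.82 with an estimated correlation. The score was -0.65 ± 0.13 in high and 0.65 ± 1.97 in low tumors (SD, n = 3 each), and low 2 alone decided it. Without low 2 the median was -0.02 with a camera adjusted p of 0.90, and without low 1 or low 3 it was -2.0 and -2.02.

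Antigen presentation genes of HLA class I and II had a median of 0.78 with 10 of 12 higher, and HLA-DMB (1.40 ± 0.36) and HLA-DMA (1.35 ± 0.36) passed adjusted over the list alone. Interferon response genes had a median of 0.43 with 15 of 18 higher, and IFIT1 (1.58 ± 0.35), IFI6 (1.5 ± 0.41), MX1 (1.26 ± 0.37) and RSAD2 (1.24 ± 0.37) passed adjusted over the list alone. Camera gave both lists adjusted p = 5.13e-05, and both had adjusted p = 0.82 with an estimated correlation. With the first region of each tumor alone the medians were 0.41 and 0.15, and the interferon call ended. The interferon median ranged from 0.20 without low 2 to 0.76 without high 2, and was 0.75 without low 1.

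Markers of T cells (median 0.50), B and plasma cells (0.54), macrophages and monocytes (0.49) and mast cells (0.65) were called higher by camera, with adjusted p-values of 0.016, 0.031, 0.0059 and 0.019. Each had adjusted p = 0.82 with an estimated correlation, and 0 of their members passed adjusted over the list alone. Members with the smallest p were TRAT1 (1.31 ± 0.63), TNFRSF17 (1.46 ± 0.61), MRC1 (1.23 ± 0.42) and HDC (1.58 ± 0.52). Without high 1 the T cell, B cell and mast cell calls ended, at -0.17, -0.31 and 0.14, and without high 3 the macrophage call ended at -0.03. Without low 3 all 4 calls ended, at 0.32, 0.21, 0.26 and 0.43. The macrophage call also ended without low 2 (0.25) and the mast cell call without high 3 (0.58), while without high 2 the 4 medians were 1.19, 1.24, 0.91 and 1.37. The T cell median was 0.81 without low 1, and the B cell median 0.83 without high 3. With the first region of each tumor the T cell, B cell and macrophage calls ended (0.40, 0.43 and 0.51), and with the other region the mast cell call ended (0.78). Cytotoxic lymphocyte (0.18) and neutrophil markers (0.14) were not called with all tumors, and camera called the cytotoxic list higher without high 2 (0.59), while its median was -0.31 without high 1. The neutrophil median ranged from -0.28 without high 1 to 0.49 without high 2.

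Fibroblast and matrix markers were lower in 14 of 17 members with a median of -0.56, including COL5A1 (-1.04 ± 0.42) and COL5A2 (-0.94 ± 0.43), and 0 members passed adjusted over the list alone. Camera gave adjusted p = 0.0053, and adjusted p = 0.82 with an estimated correlation. The call ended without high 2 (-0.25), without low 2 (-0.17) and with the first region of each tumor (-0.28). Immediate early and handling stress genes, which respond within minutes to tissue handling, were higher in 18 of 20 members with a median of 0.57, and 0 members passed adjusted over the list alone. DUSP1 lay at 1.69 ± 0.44, FOS at 1.64 ± 0.57, and the heat shock genes HSPA1A and HSPA1B, which are near-identical copies, at -1.06 ± 0.49 and -1.23 ± 0.35. Camera gave adjusted p = 0.0050, and adjusted p = 0.82 with an estimated correlation. Without high 3 the median was 0.08 and the call ended, and without high 2 it was 0.97. Lists of the epithelial-mesenchymal transition (median -0.17), the unfolded protein response (-0.09), inflammatory cytokines and chemokines (-0.26) and lung muscle and nerve stroma (median -0.20, mean 0.22, camera direction higher) were not called with all tumors. Without high 3 camera called the transition list (-0.46) and the cytokine list (-0.65) lower. Without high 2 the medians of the cytokine and stroma lists were 0.30 and 0.46. The unfolded protein response ranged from -0.37 without high 2 to 0.02 without low 3. PTGS2, a prostaglandin synthase, was the 1 cytokine list member that passed adjusted over the list alone (-1.60 ± 0.39). Ribosomal protein genes had a median of 0.05 and a mean of -0.0020 and were not called with all tumors, and the list was called in opposite directions without low 1 (-0.30) and without low 3 (0.39).

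On average the 2 regions of a tumor resembled each other more than regions of different tumors did, with exceptions in high 3. Across genes, the mean Pearson r between the regions of the 4 tumors with 2 libraries was 0.946 (0.911 to 0.958). Over the 24 pairs of these libraries from different tumors it was 0.883 (0.834 to 0.932). Genes within a library are not independent replicates, so the test permuted the pairing of libraries. The true pairing had the highest mean of all possible pairings, an exact one-sided permutation p of 0.0095. In the 6 low libraries alone r was 0.957 within and 0.883 between tumors, the highest of 15 pairings (exact one-sided permutation p = 0.067, the smallest 15 pairings allow). The consensus correlation of the regions of 1 tumor, after the group means were removed, was 0.58. The regions of high 3 were the least alike pair, at 0.911. Both were closer to region b of low 1, at 0.921 for region a and 0.932 for region b, and region b also to high 1 (0.925). Across groups, high 1, which had 1 library and is not in the 24 pairs, reached 0.954 with region b of low 1. Depth was 9062512 fragments in region a and 8315620 in region b of high 3. It was 15909736 in region b of low 1 and 21531638 in high 1. Whether depth contributed to these values of r was not tested.

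**Figure D3:**
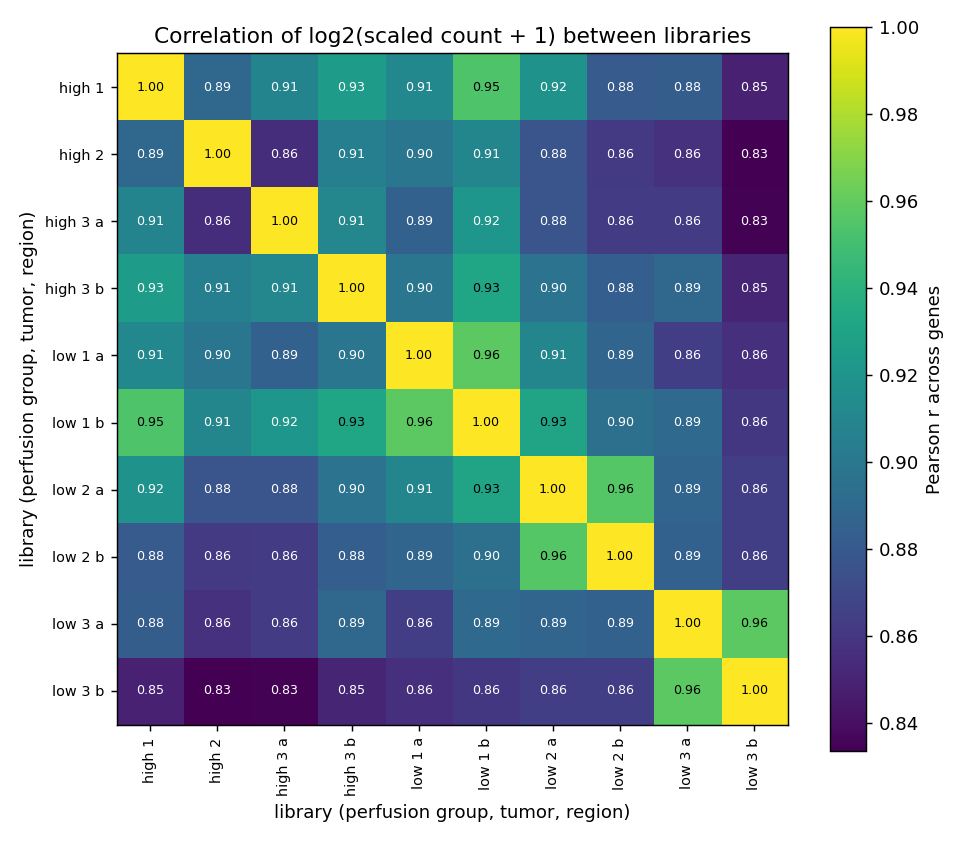
Pearson r across the 16604 tested genes between each pair of the 10 libraries, on log2(scaled count + 1), with libraries named by perfusion group, tumor and region on both axes and r as color and number. The regions of the 3 low tumors reach 0.96 with each other, and the regions of high 3 reach 0.91.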

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

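The outlier screen was fixed beforehand, while the tests of tumor cell share, of other splits of the tumors and of MALAT1 were chosen after those results had been seen. Of 186 group tests for 1 library far from the others, 9 came out positive, and about 9.3 would by chance if libraries were independent. Regions of 1 tumor are not independent, so that number is uncertain, and the screen can miss a tumor whose 2 regions stand apart together. The neuroendocrine scores of low 2, 2.88 and 2.96 against -0.70 to -0.42 in the other low libraries, were not flagged. The gap of the extreme library to its nearest neighbour, as a share of the group's range, was 0.974 for the glutamine and glutamate list, 0.949 for the pericyte and smooth muscle list, 0.839 for MUC6, 0.87 for CRYM, 0.909 for PC, 0.890 for PDHA1 and 0.845 for SLC16A3, each in the 4 high libraries. In the 6 low libraries it was 0.687 for the lung muscle and nerve list and 0.660 for ALDH1A1. The extreme library was the highest for MUC6 (10.97 against 9.29 on the log2 scale), PC, PDHA1, SLC16A3 and the lung muscle and nerve list, and the lowest for the other 4. Loci with no gene name, which enter the comparisons above in 1 alternative alone, held a median of 6.67% of the scaled counts, and of 11115 such loci tested 0 passed limma's adjusted threshold and 789 had an unadjusted p under 0.05, 380 of them higher in high perfusion.

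The first pattern was the lower cell cycle message in high perfusion. A difference in depth is argued against, since after every library was thinned to 5013010 fragments the list's median was -1.54, with 30 of 30 members below 0. A trend with abundance and transcript length is argued against too, since the median after subtracting that trend was -1.56. Single tumors also differed in marker scores, such as 2.92 for neuroendocrine markers in low 2 and 1.63 for squamous markers in low 3. A difference in tumor type between the groups was not tested and stays open. A lower share of tumor cells in the high-perfusion samples cannot be told apart from lower proliferation. If a lower share raised markers of every other cell type alike, all 6 lists tested would be higher. The lowest of them, fibroblast markers, lay only -0.834 standard errors from 0, so the spread between 3 and 3 tumors keeps a lower share open. A rise of 1 other component alone, such as normal lung, need not raise these lists and was not tested. Left out of the 6 were alveolar type 1 (median 0.55), airway (0.97), alveolar type 2 (0.30) and lung muscle and nerve lists (-0.20). Perfusion itself stays open as untested.

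Splits of the 6 tumors are too few (10) for a share under 0.05. The real split gave 0 genes past the adjusted threshold against at most 1 in the others (10 of 10 as large), 924 against at most 1211 genes at an unadjusted p under 0.05 (3 of 10 as large), and 19 against at most 21 lists (5 of 10 as large).

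The second pattern was that alveolar type 2 markers differed between the 2 regions of 1 tumor, by a mean of 1.55 ± 0.42 (SD, n = 4 tumors). Single libraries of different tumors in 1 group differed by 0.98 ± 0.70 (SD over 17 pairs that share libraries), and the excess was not tested. Depth is argued against, since depth and these markers differed in the same direction in 2 of 4 tumors. A different share of normal lung tissue in the regions may contribute, since alveolar type 1 markers differed in the same direction in 4 of 4 tumors, with a mean gap of 0.60. Chance gives 4 of 4 in 6.25% of cases, and a surfactant program of tumor cells was not tested and stays open. The most abundant of the 12 members were SFTPB, at 33240 scaled counts with a mean gap of 1.95, and SFTPA2, at 11562 with a gap of 2.40. Several other lists also differed more between regions than between single libraries of different tumors, while most lists differed less. Among the former were red blood cell transcripts (0.81 against 0.45) and alveolar type 1 markers (0.60 against 0.44).

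The third pattern was MALAT1, an abundant nuclear RNA singled out after its values were seen. It was listed at 0 in 7 of 10 libraries in both tables, and at 780575 in 1 high and 661775 and 453817 in 2 low libraries. A failed estimate in the authors' quantification may account for this, since 0 libraries lay between 0 and 453817 and 3 tumors had 1 region at 0 and the other not. The locus of NEAT1, another nuclear RNA, ranged from 52744 to 188937. No biological explanation was tested.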

How the results depend on the processing

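The planned count test, edgeR, was not run because the deposited counts were already scaled, and DESeq2 was not run either. Limma-voom on the recovered fragments, pseudocounts of 0.1 and 5, the highest locus per name and the inclusion of unnamed loci were chosen after seeing the data. The gene count was 0 in 20 of 21 alternatives and 6, all lower in high perfusion, with the 10 libraries as if independent, which counts regions as replicates. Genes at an unadjusted p under 0.05 numbered 642 to 1972. The list count was 11 with the first region of each tumor, where the cause was not tested, and 0 with an estimated correlation and with fry, which allow for correlated genes. It was 14 to 22 with 1 tumor left out. The panel count was 0 to 1 with 1 tumor left out, the 1 without low 1. In the 6 low libraries the mean r within tumors exceeded that between tumors by 0.074, which was not past the threshold there, because 15 pairings are too few. With 1 tumor left out, the medians of 20 lists changed sign. Of these, 4 were called with all tumors, oxidative phosphorylation (-0.59 to 0.04), T cell (-0.17 to 1.19), B and plasma cell (-0.31 to 1.24) and macrophage lists (-0.03 to 0.91). The endothelial (-0.36 to 0.36) and ribosomal lists (-0.30 to 0.39) were called against their direction with all tumors in 1 such setting each. The cause was not tested. Among 895 comparisons of single lists, 74 lost a call, 17 gained one and 4 reversed. These 4 are changes of camera's direction where a call was made with all tumors or in the alternative, and with uncalled lists included there were 56. Of 3906 comparisons of single genes, 6 gained a call and 38 changed direction, all of them of genes not called. The median log2 fold change of all genes moved by under 0.1 with either other scaling. No paired analysis was possible because perfusion did not vary within a patient. Depth limits low genes most in the library of 5369186 fragments.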

Other observations

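The direction in which the regions of a tumor differed in alveolar type 2 markers was shared by several other lists in all 4 tumors with 2 regions. The mean gap between regions was 0.81 for red blood cell transcripts, 0.66 for the interferon response, 0.63 for endothelial markers, 0.62 for antigen presentation, 0.52 for cytotoxic lymphocyte markers, 0.50 for neutrophil markers and 0.40 for glandular epithelial markers. Squamous keratinocyte markers (1.07), the hypoxia response (0.20) and neuroendocrine markers (0.15) differed in the opposite direction in all 4. Of the other 38 lists, 8 went the same way and 3 the opposite way in every tumor, where chance gives about 2.4 each. The lists are not independent, and the glandular list shares 2 members with the alveolar type 2 list. Cell cycle genes went the same way in 2 of 4 tumors, with a mean gap of 0.34.

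A hypothesis stated before its test was that tumors with less endothelial message have more hypoxia message. Across the 6 tumors Pearson r between the endothelial and hypoxia scores was -0.193 (exact permutation p = 0.71) and Spearman's rho was -0.20 (exact permutation p = 0.71), in 1 relation computed. Without the 2 tumors farthest from the median endothelial score r was -0.69. These tumors are too few to decide it.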
